A study of Gossypium hirsutum with 2 samples.

How the data were processed

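DNA affinity purification sequencing was done with GhD53 on genomic DNA of cotton fiber, with 1 affinity-purified library and 1 input library. Groups were taken from the fraction named in the labels. The labels' protocols describe a protein with an affinity tag expressed in vitro, a library made from extracted genomic DNA, and separation of the protein-bound fragments. The submitters' processing notes name BWA, ChIPseeker and deepTools 2.5.4. The peak caller, the genome build, read filters and thresholds are not given in the sources used here, and coordinates are printed as the files give them. Library totals were not used here, so depth is described only by the pileup at each peak.

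The data were 2 peak lists of the purified against the input library, restricted to promoters by their names. Per the file headers, each peak has a pileup (the fragment signal at the summit in the purified library), a fold enrichment (a ratio over the background), and a −log10 p-value and −log10 q-value, all deposited by the authors. The authors also deposited the nearest gene, its feature class, the distance of the peak centre to the gene's start site, a best protein hit with its description and a transcription factor family. No per-replicate peaks were called, since each fraction had 1 library. The lowest −log10 q was 1.31 in the shorter list and 0.917 in the longer list, and the lowest −log10 p 3.84 and 3.10; these are the lowest values observed, not stated thresholds. The shortest peak was 131 bp in both.

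From these values the background was recovered as (pileup + 1) / fold − 1, and a Poisson tail on this background gave the deposited −log10 p to within 0.000188 for 2181 of the 2183 longer-list peaks; the remaining 2 were beyond the numerical range. The gene given by the authors was used for each peak. In the longer list 2134 peaks were annotated to the promoter of that gene and 49 were not, most being promoter peaks of a neighbour. Gene names came from the best protein hits, and 858 of the 2111 longer-list genes had none that was informative. A gene was taken to have an organelle description where its best hit was a record marked as encoded in a plastid or mitochondrial genome, or carried a plastid-encoded gene's name under a bacterial entry or in a short list of names, a wording chosen after the data were examined. Nuclear genes for proteins sent to an organelle, described as chloroplastic or mitochondrial, were not included, and some plastid-type names, such as photosystem II protein D2 at GH_D08G1324, were missed.

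Overlap needed 1 bp and was checked with bedtools 2.31.1. It was compared with 1000 random placements in which the shorter list's distances were redrawn over the genes of the longer list. Strength was compared by medians with a two-sided permutation test of 100000 resamples, and correlations were taken across peaks. Shares have Wilson 95% intervals, which cover counting error only. The 27 gene lists were fixed by words before the data were examined, and transcription factor lists used the authors' family column except the homeobox-leucine zipper list. The histone list was read as core histones. An annotation with the same gene identifiers was not used here, so lists were tested between genes in both lists and genes in the longer list alone, as planned for that case. For the same reason the planned redraw of genes for homoeologs was replaced by shuffling chromosome numbers among the named D genes, and by the share of D genes with a peak, taken over the highest gene numbers seen per chromosome (35371 on A and 35484 on D in total). Peaks per subgenome in the full sets came from the numbers in the peak names, which rose along every chromosome. The motif comparison was not run.

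The genes named were those of the 10 strongest peaks by fold in each list, those of the 10 strongest overlapping pairs, every strigolactone and karrikin gene with a peak, and for each other list up to 4 genes in both lists, or in either where none was in both, with the highest fold; unnamed genes were given by identifier, at most 2 per list. Alternatives were a q-value of 1e-05 or lower, the stronger part by fold, merged peaks, reciprocal overlap of 50%, centres within 100 bp, equal list lengths, significance in place of fold, log2 values, recomputed distances, genes in place of peaks, and peaks within 1000 bp upstream. The procedures were tested on simulated data. Of 600 peaks with 400 left in place the overlap step recovered 400. Random labels were drawn over the 2183 longer-list peaks, and a gene took the label if any of its peaks had it. Over the 2111 genes they gave 1 call in 1350 list tests. A planted list was called in 50 of 50 draws, and all 100 planted homoeolog pairs among 595 A genes were recovered. The planted list joined the pentatricopeptide repeat and ethylene names and carried a strong effect, so it does not speak for short lists or small differences. The planted homoeologs were given identical descriptions, so their recovery tests only the matching step. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.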

Results

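GhD53 is the upland cotton (Gossypium hirsutum) member of the D53 family of strigolactone signalling repressors. Its binding to DNA was measured by DNA affinity purification sequencing, in which a tagged protein made in vitro is mixed with naked genomic DNA and the bound fragments are sequenced. The DNA came from cotton fiber, the single-celled seed hair that is spun as cotton. There was 1 affinity-purified library and 1 input library, so there is no replicate spread, and each p-value below describes peaks or genes within this single comparison. The comparison asks which promoters were enriched with the protein in vitro. No purification without the protein was among the libraries. Enrichment over input therefore cannot separate binding by GhD53 from other effects of the purification. The deposited results were 2 lists of promoter peaks called for the same purified library against the same input. They are called the shorter and the longer list here. Pileup, fold enrichment and q-value of every peak are the authors' own values.

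The shorter list held 756 promoter peaks at 725 genes and the longer list 2183 peaks at 2111 genes, on all 26 chromosomes. Most peaks were low. The median pileup at the summit was 7 fragments in the shorter list (quartiles 6 and 9.25) and 5 in the longer list (quartiles 5 and 6), with median folds of 4.98 and 3.73. In the longer list 1925 peaks, or 88.2%, had a pileup of 4 to 8, against 524 (69.3%) in the shorter list. The recovered background stood at its lowest value, 0.608, under 1845 peaks of the longer list (84.5%). The lowest pileups in the lists were 5 and 4 fragments, so at this depth the absence of a gene was not evidence that its promoter was unbound. A q-value of 1e-05 or lower was reached by 214 and 227 peaks.

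All 756 peaks of the shorter list overlapped a peak of the longer list, against a mean of 163 and a maximum of 195 in 1000 random placements within promoters. The lists were not independent measurements, so an overlap beyond random placement was given by their origin: 744 pairs had the same summit with identical pileup, p-value, fold and q-value, and in each of these the shorter-list peak lay inside the longer-list peak. Across the 756 pairs, which are peaks and not samples, Pearson's r of the folds was 0.993 and Spearman's rho 0.991, which follows from the identical values. The 752 longer-list peaks with a partner had a median fold of 4.98, against 3.73 for the 1431 without one, a difference of 1.24. The shorter list starts at a higher pileup and significance, so this difference is given as a description and not as a test. Of those 1431 peaks, 976 nevertheless had a q-value of 0.05 or lower. Among peaks of pileup 6 on the lowest background with such a q-value, the 158 found in both lists had a median length of 193.5 bp and the 240 found in the longer list alone 164.5 bp (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). As the lists were not made independently, this length difference too describes how they differ and is not a test of binding. All 725 genes of the shorter list were in the longer list, and 1386 genes were in the longer list alone.

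The strongest promoter peaks stood well apart from this low majority, and the 10 with the highest fold belonged to the same 10 genes in both lists. Values are those of the longer list. The recovered background was raised under some of these peaks. It was 17.1 at GH_D02G1277, 11.7 at GH_A05G4214, 8.92 at GH_A05G3311, 4.08 at GH_D03G0158 and 3.57 at GH_A08G2618. At the others it lay between 0.608, its lowest value, and 0.971. The highest fold, 25.5, was on chromosome A05 (65842775 to 65843079), 1326 bp upstream of GH_A05G3311, described as a plastid-type ribosomal protein L14, with a pileup of 252. GH_A08G2618, described as a WHY2-like mitochondrial single-stranded DNA-binding protein, followed at 24.5-fold with a pileup of 111, its peak lying 630 bp upstream. The promoter of GH_A04G1309, a FAD synthetase, reached 21.5-fold (pileup 37), and that of GH_D03G0158, an indeterminate-domain 2-like zinc finger factor, also reached 21.5-fold (pileup 108, 805 bp upstream). GH_D02G1277, described as plastid ribosomal protein S11, had 13.6-fold, the predicted disease resistance gene GH_A01G0185 had 13.1-fold, and GH_A05G4214, encoding a Mediator 26c-like subunit of the RNA polymerase II coactivator, had 12.3-fold. Of the 3 remaining genes, which carry no informative name, GH_A04G0257 had 15.2-fold and GH_D11G2764 14.3-fold.

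In the strigolactone and karrikin pathway list 2 genes had a peak, both in the longer list alone and both at the lowest pileup there, 4 fragments and 3.11-fold with a −log10 q of 0.917. They were GH_A05G0420, a CYP711A1-like cytochrome P450 of the family that makes strigolactones from carlactone (1224 bp upstream), and GH_A02G1790, annotated as a D14L esterase, the karrikin receptor type (106 bp upstream). No D53 family gene was matched. Among branching and architecture genes 3 had a peak and 2 of these were in both lists: GH_A11G0398, a squamosa promoter-binding-like 13A factor, at 4.98-fold (1709 bp upstream), and GH_D12G2026, a TCP17-like factor, at 3.96-fold (241 bp upstream).

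Genes with wall-related descriptions were present but mostly at low folds. Their role in fiber was not tested. Of 14 secondary wall and cellulose genes with a peak, 3 were in both lists: the cellulose synthase-like D4 gene GH_D04G1673 (6.84-fold, pileup 10), the xylan synthesis gene GH_D12G2140 (IRX10L, 4.35-fold) and the fasciclin-like arabinogalactan gene GH_A06G1305 (4.35-fold). The only member of the cellulose synthase A family with a peak, GH_A07G2317, encodes catalytic subunit 4 of the secondary wall complex; it had 3.73-fold in the longer list alone and was chosen after its value was seen. Of 7 wall loosening genes, 2 were in both lists, a pectinesterase (GH_A11G1186, 4.46-fold) and a xyloglucan endotransglucosylase/hydrolase (GH_D02G1499, 4.35-fold). Of 6 fatty acid and lipid genes, 2 were in both lists: the FAD2-like desaturase GH_D11G3608, which makes linoleic from oleic acid (5.60-fold), and GH_A10G1273, a 3-ketoacyl-CoA synthase of very-long-chain fatty acid elongation (4.35-fold).

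Among the hormone lists, ethylene held the most genes, 18. Nearly all were AP2/ERF transcription factors matched by name, so this count does not rank ethylene above other hormones. Of the 18 genes, 5 were in both lists. Those with the highest folds, all 4.35-fold, were GH_A12G1267 (CRF6-like), GH_A10G1351 (ERF062-like), GH_D06G0690 (TINY-like) and GH_D11G0816. Auxin had 3 genes. The SAUR-type GH_D12G0308 (4.35-fold) and GH_A03G2260 (3.97-fold) were in both lists, but the latter peak lay 910 bp downstream of that gene's start site and was annotated to the promoter of its neighbour. The 3 brassinosteroid genes were in the longer list alone, led by GH_D09G0890, a shaggy-related kinase eta (BIN2 type), at 4.35-fold, with the receptor kinases GH_A05G0098 and GH_D13G0570 at 3.11-fold. Abscisic acid had 7 genes with 1 in both lists, the protein phosphatase 2C gene GH_A03G1985 (4.53-fold). Cytokinin had 2, an isopentenyltransferase (GH_A08G0757, 3.73-fold) and a type-A response regulator (GH_D10G2057, 3.47-fold). Jasmonate had 1, the TIFY 5A-like repressor GH_D10G0454 (3.11-fold), also with a pileup of 4 and a −log10 q of 0.917. No gibberellin gene was matched.

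The authors' annotation assigned a regulator family to 156 genes of the longer list (7.39%) and 61 of the shorter (8.41%). Zinc finger factors (C2H2 and C3H) had 16 genes, 7 of them in both lists. After GH_D03G0158 came GH_A12G2372 (ZAT9-like) and GH_D12G1721 (SHOOT GRAVITROPISM 5-like), both 5.60-fold, and GH_A05G0623, a CCCH protein at 4.98-fold. Of 10 NAC genes 5 were in both lists, led by GH_A09G1390 (6.22-fold), a NAC29-like factor, ahead of GH_A01G0581, a CUP-SHAPED COTYLEDON 2-like boundary factor, GH_A09G2020 and the ATAF2-like GH_A06G1138, all at 4.35-fold. MYB factors had 14 genes and 3 in both lists, with GH_A12G1832 (MYB122-like) at 6.22-fold and GH_A06G1476 (MYB3-like) at 4.98-fold. Of 9 WRKY genes 3 were in both lists (GH_A05G2470, GH_D03G0476 and GH_D06G2111, each 4.35-fold). The bHLH, homeobox-leucine zipper and MADS lists had 4 genes each with 2 in both lists. They were led by GH_A03G2266 (bHLH121-like, 6.84-fold), GH_A01G2273 (ATHB-22-like, 5.60-fold) and GH_D13G1541 (AGL80, 6.84-fold). Of 4 bZIP genes, 1 was in both lists.

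No gene list was found to differ between the 725 genes in both lists and the 1386 in the longer list alone. The test was a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 27 lists, and 1 list had an unadjusted p below 0.05. That was the ribosomal protein list, with 22 of its 37 genes in both lists (odds ratio 2.86, Fisher's exact p = 0.00242, adjusted p = 0.0653). Of the 37, 22 had an organelle description. That means a best hit marked as encoded in an organelle genome, or one with a plastid-encoded gene's name as defined above. Without organelle descriptions 3 of 15 were in both lists (odds ratio 0.506, Fisher's exact test, adjusted p = 1). Many lists held fewer than 10 genes, where the test could show only a large difference. Lists of 4 genes or fewer could not have passed whatever their split, and the gibberellin list held 0 genes. In the other reference lists, 11 of 21 pentatricopeptide repeat genes, 9 of 17 disease resistance genes, 5 of 9 photosystem genes, 1 of 3 proteasome genes, 1 of 4 histone genes and 1 of 8 retrotransposon-related genes were in both lists. All 5 photosystem genes in both lists, GH_D03G0877 included, had an organelle description, and of the 3 photosystem genes without one 0 were in both lists. The highest folds of these 6 lists among genes in both lists were, in that order, 8.71 (GH_D05G3727), 13.1 (GH_A01G0185), 6.45 (GH_D03G0877), 4.98 (GH_A11G1820), 4.98 (GH_D08G0502) and 3.97 (GH_A12G1373). These tests set peaks against peaks; how common each group is among all promoters was not analysed here.

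Nuclear loci with an organelle description carried the highest pileups. Nuclear genes for proteins sent to organelles, such as GH_A08G2618, are counted with the other genes. In the longer list 81 peaks at 55 such genes, 3.71% of all peaks, made up 46.5% of the summed pileup, with a median pileup of 137 against 5 at other genes. Their background was high as well (median 38.3 against 0.608), so their median fold, 3.30, was below the 3.73 of other genes. They provided 79 of the 116 peaks with a pileup above 20. The largest pileup, 748, was 674 bp upstream of GH_A12G0231, another L14-type gene, where the fold was 11.7. Fold differed between plastid genes. The median was 9.67 over 4 loci named for rpl14 and 8.58 over 6 loci named for rps3, but 2.12 over 3 loci named for rpl2 and 4.06 over 4 loci named for psbB.

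**Figure D1:**
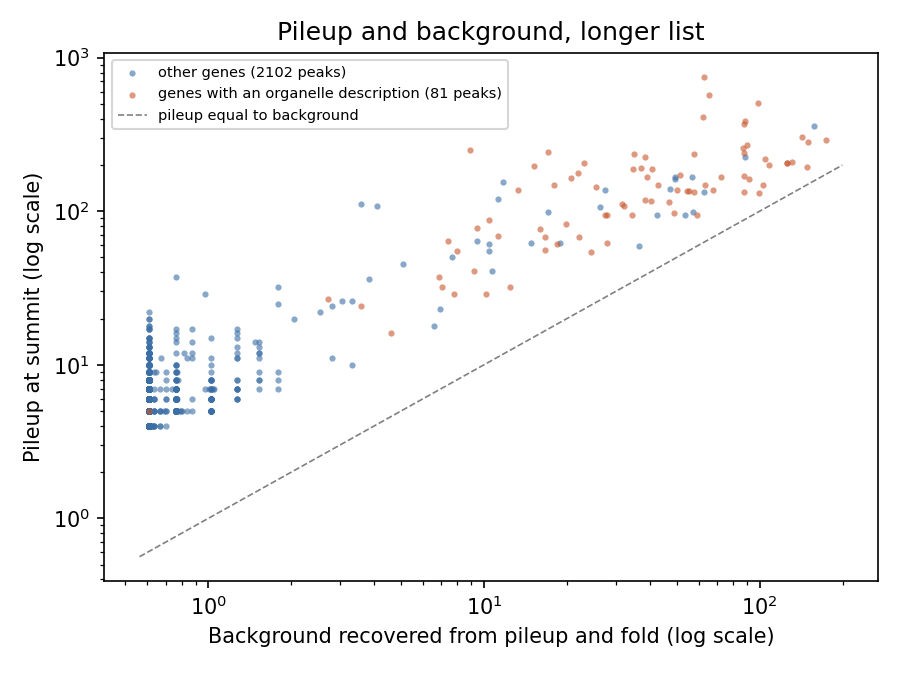
Each point is a peak of the longer list, with the background recovered from the authors' pileup and fold on the x axis and the pileup at the summit on the y axis, both on log scales. The 81 peaks at genes with an organelle description lie mostly at high pileup and high background, and 1845 peaks stand at the lowest background of 0.608.

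**Figure D2:**
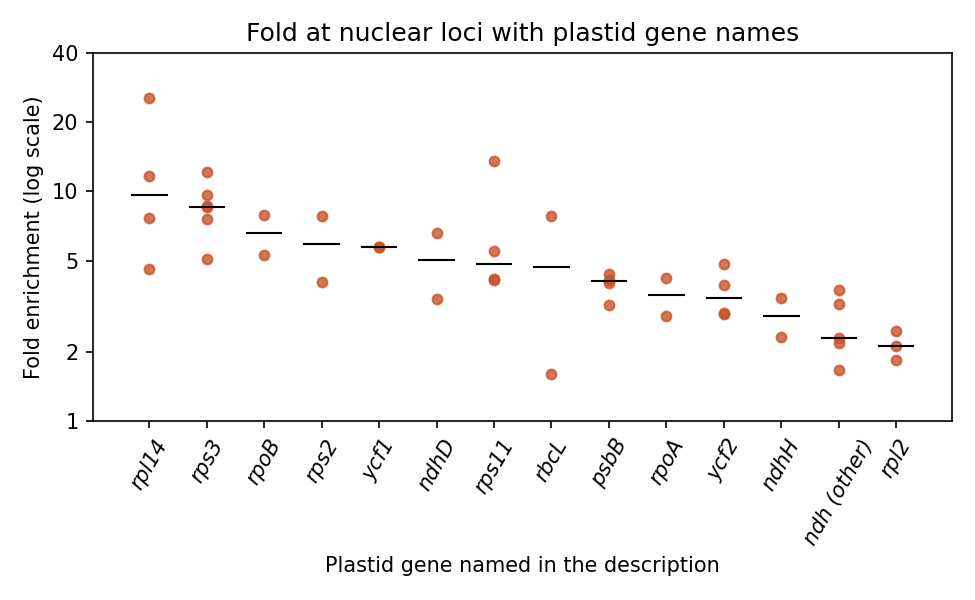
Fold enrichment on a log scale at loci whose description names a plastid gene, 1 point per nuclear gene with its strongest peak, grouped by plastid gene with the median as a line. The medians run from 9.67 for rpl14 to 2.12 for rpl2, and the 4 rpl14 loci spread from 4.58 to 25.5.

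Peaks thinned out toward the start site. Of the 2099 longer-list peaks centred within 2000 bp upstream, 13.8% (Wilson 95% interval 12.4 to 15.4) lay in the nearest 500 bp and 31.4% (29.4 to 33.4) in the farthest 500 bp, that is 58 and 131.8 peaks per 100 bp of distance. The gradient was steeper in the shorter list, with 11.9% (9.69 to 14.4) and 37.8% (34.3 to 41.4) of 717 peaks. The nearer 1000 bp held 34.6% of the shorter-list peaks and 41.6% of the peaks found in the longer list alone (odds ratio 0.744, two-sided Fisher's exact test, p = 0.00188). Each share was below an even split (exact binomial test, p = 1.21e-16 and 3.54e-10). Without the 250 bp nearest the start site, an alternative chosen after seeing the data, the nearer part held 38.3% of the shorter-list peaks (exact binomial p = 8.32e-10) and 46.7% (44.0 to 49.4) of those in the longer list alone (p = 0.0189). Examples at the 2 ends were the karrikin receptor-type gene GH_A02G1790, with its peak 106 bp upstream, and the AGL80 gene GH_D13G1541, with its peak 1963 bp upstream.

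**Figure D3:**
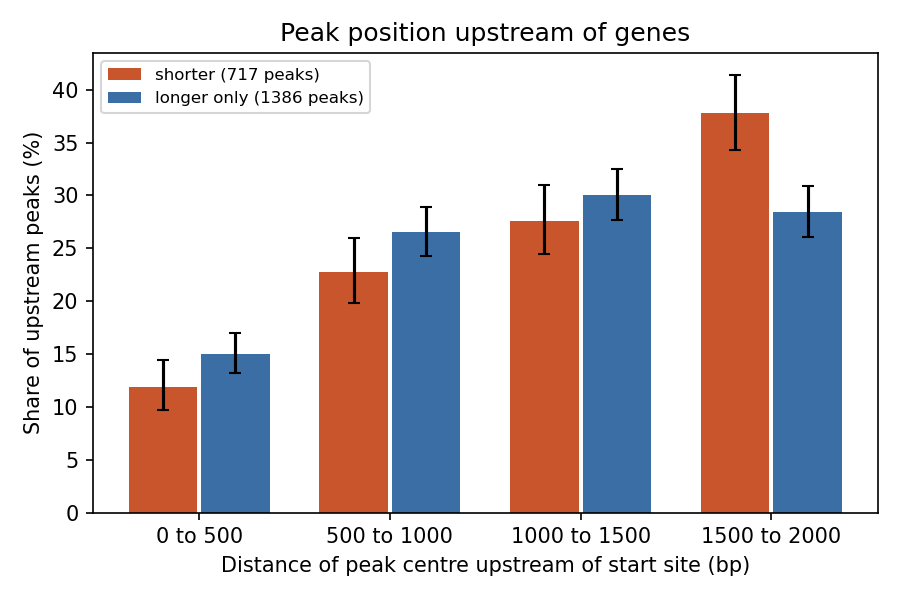
Share of upstream peaks in 4 distance classes of 500 bp, for the shorter list (717 peaks) and for peaks in the longer list alone (1386 peaks), with Wilson 95% intervals as error bars. Both rise away from the start site, from 11.9% to 37.8% in the shorter list and from 15.0% to 28.4% in the other set, whose highest class is 1000 to 1500 bp at 30.0%.

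Upland cotton carries an A and a D subgenome, and promoter peaks were split evenly between them: 383 on A and 370 on D in the shorter list (exact binomial test, p = 0.662), 1088 and 1089 in the longer list (p = 1). The Wilson 95% interval of the A share in the longer list was 47.9% to 52.1%. The peak names point to a less even split of the full peak sets. Their numbers rise along the chromosomes and reached 22881 and 66762. If they count every called peak in genome order, which the sources used here do not state, promoter peaks were 3.30% and 3.27% of all peaks. On that reading at least 46164 peaks lay on A and 19380 on D chromosomes in the longer set, an A share of 70.4%, and the promoter share was 2.36% on A and 5.62% on D. The promoter split differed from the split of all numbered peaks (exact binomial test, p = 1.15e-88), though neighbouring peaks are not fully independent. The highest gene numbers were nearly equal on A and D (35371 and 35484), while the chromosome spans were 1417 and 812 Mb. Promoter peaks per 1000 gene numbers were 30.8 on A and 30.7 on D. A difference between the 2 splits was therefore likely beforehand, and the p-value is not evidence that promoter binding differed by subgenome.

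**Figure D4:**
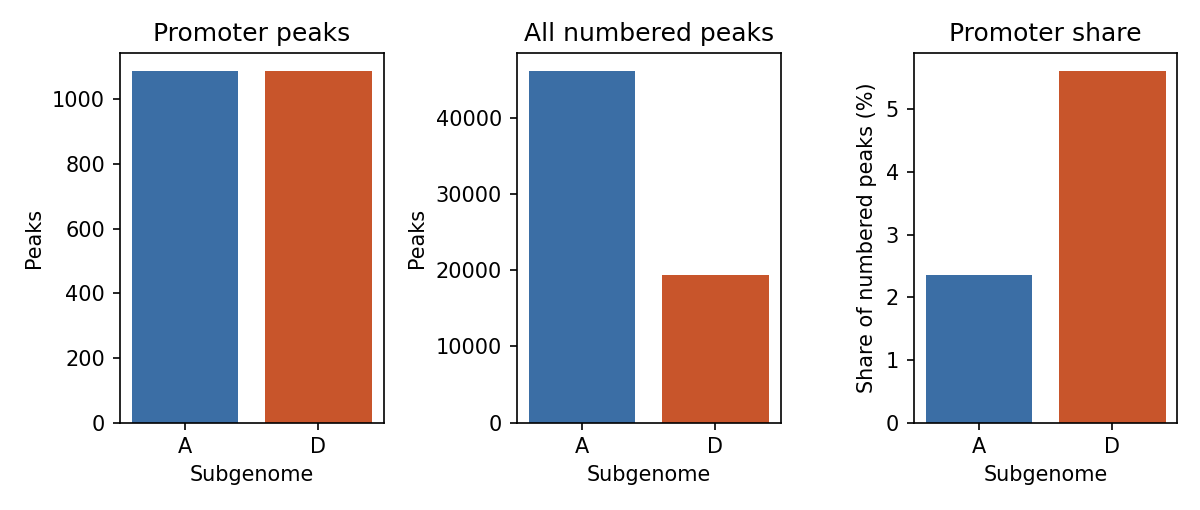
Counts for the A and D subgenomes in the longer list: promoter peaks on the left, all peaks implied by the peak numbering in the middle, and the percentage of numbered peaks that were promoter peaks on the right. Promoter peaks were 1088 and 1089, while numbered peaks were 46164 and 19380.

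Homoeologs, the A and D copies of a gene, seldom both had a peak. Of 595 named A genes in the longer list, 20 (3.36%, Wilson 95% interval 2.19 to 5.13) had a D gene with the same description and a peak on the same-numbered chromosome. These 20 genes were more than the mean of 5.54 when chromosome numbers were shuffled among the D genes. The highest of 1000 shuffles was 16 (one-sided permutation p = 0.001, the smallest they can give). Homoeologs that lie on same-numbered chromosomes would give such an excess even if their peaks were independent. The share of 3.36% was not distinguishable from 2.99%, the share of all D genes that had a peak (two-sided exact binomial test, p = 0.547). That is the share if A and D copies were hit independently and every copy was matched. The pairs included the cellulose synthase-like D4 genes GH_A04G1334 (3.11-fold, 928 bp upstream) and GH_D04G1673 (6.84-fold, 839 bp upstream). They also included the CRF6-like genes GH_A12G1267 (4.35-fold) and GH_D12G1283 (3.11-fold), and the indeterminate-domain 12-like genes GH_A08G0705 and GH_D08G0698 (4.98-fold and 4.35-fold). GH_A04G1334 and GH_D12G1283 had a pileup of 4, the lowest in the longer list. So did GH_A06G1492, GH_A11G3396, GH_A13G0843 and GH_A13G2169 in other pairs. Peaks of this pileup and 3.11-fold, such as that of GH_A02G1790, had a −log10 q of 0.917, the lowest there. Each of these pairs thus includes a peak at the bottom of that list. In the shorter list 2 of 194 A genes had a D partner, which did not pass the shuffle test (mean 0.428, highest 3, one-sided permutation p = 0.056). Copies whose descriptions differ, or that lie on differently numbered chromosomes, were not paired. Genes that share a description without being homoeologs were paired, so the count can err in either direction. Some counted peaks were not upstream. Those of the pair GH_A03G0052 and GH_D03G1912 lay 855 and 617 bp downstream of the start site, and that of GH_A13G2169 lay 3 bp downstream. In another pair GH_D11G1644 had a pileup of 226 at only 2.53-fold.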

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

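The alternatives without organelle descriptions and without the 250 bp nearest the start site were chosen after seeing the data; the others were planned. Counts followed the threshold. At a q-value of 1e-05 or lower the shorter list kept 214 peaks at 199 genes and the longer list 227 peaks at 205 genes, and the stronger part by fold was 378 peaks at 372 genes and 1091 peaks at 1072 genes, by construction of these filters. Merging changed neither list. The overlap (70.4% of the shorter list at equal list lengths, 97.0% to 100% otherwise) exceeded every random placement, and the strength difference and the correlation (0.985 to 0.9999) kept their direction; all 3 could hardly do otherwise, since 744 pairs carry identical values and the shorter list holds the stronger peaks. The gradient away from the start site kept its direction in both lists (32.2% to 43.9% in the nearer part); in peaks of the longer list alone it shrank to 46.7% (exact binomial test, p = 0.0189) without the nearest 250 bp. The A share changed side without passing the exact binomial test: 49.3% without organelle descriptions in the shorter list (p = 0.732) and 54.9% at the stricter q-value in the longer list (p = 0.162); the cause was not tested. No gene list passed within 1 kb upstream or without organelle descriptions. The stricter q-value left 6 genes in the longer list alone, too few to say anything about stability; the odds ratio of 0.223 of the ribosomal protein list there rests on 2 genes, with 20 of 22 in both lists. Without organelle descriptions, where 22 of its 37 genes are removed, that ratio was 0.506. The homoeolog share was 1.03% in the shorter list, where fewer genes have a peak, and its excess over shuffled partners no longer passed (one-sided permutation p = 0.056). Of 46 alternative values, 33 were called unchanged, a count that includes those that could hardly change. For tested values this meant the same direction and side of the threshold. For counts of peaks, genes or passing lists it meant an equal or similar number. The motif alternatives were not run, and the group test on genes in both lists only gives no value, since it leaves nothing to compare with. No paired analysis was possible because each fraction had 1 library. The pileup of 4 to 8 fragments under most peaks limits all of these comparisons.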

Other observations

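The share of homoeologs with peaks was planned, while its comparison with the independent rate and the other tests in this part were chosen after the values had been seen. The gene groups in this paragraph were also picked after their values were seen, and apart from GH_D03G0158 their genes had pileups of 4 to 9. The Topless-related gene GH_A08G2546 had a peak in both lists at 4.98-fold, 469 bp upstream, and 3 histone deacetylase genes had one. The histone deacetylase 14-like GH_A05G4038 was in both lists (4.35-fold), while the 19-type GH_A12G1773 (4.35-fold) and the 6-like GH_A03G0747 (3.11-fold, pileup 4) were in the longer list alone. Genes with indeterminate-domain in their description numbered 6 with a peak, 5 of them in both lists. They ran from GH_D03G0158 at 21.5-fold and GH_D05G3819 at 6.22-fold to GH_A09G1891 at 3.11-fold. Family members described under another name were not counted. No enrichment of these groups was tested.

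Organelle-type loci held 46.5% of the summed pileup. A uniform excess of organelle DNA in the purified library would give similar folds only at loci with a similar background and a similar part of reads from organelle DNA. The loci tested were 44 in 14 groups by plastid gene name, 1 of them pooling ndh-type hits with no gene given. Of the variance of log2 fold, 64.3% lay between groups, more than with shuffled names (permutation p = 0.00051). Names were shuffled without regard to the background at each locus, and the 4 rpl14 loci alone spread from 4.58-fold to 25.5-fold. The test therefore cannot decide whether a uniform excess was the cause. Neighbouring loci of 1 insertion are also not independent. Binding that differs along plastid DNA may explain the differences between groups, and so may reads shared between near-identical copies or segment-specific library bias. All of these stay open.

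If the peak numbers count all called peaks, these favoured the A subgenome. Chromosome length alone would give 63.6% by the span of the chromosomes, below the observed 70.4% (Wilson 95% interval 70.1 to 70.8). Weak peaks as the source stay open: the shorter set had 71.0% on A, but 69.3% of its own promoter peaks had a pileup of 4 to 8, so it cannot tell. Promoter peaks were also fewer than the length of promoters would give: windows of 2000 bp per gene would cover 4.99% of A and 8.74% of D, against promoter shares of 2.36% and 5.62% of numbered peaks. Repeats, which differ between the subgenomes, may contribute to both, but this was not tested, and the annotation of peaks to other features could lower the promoter share. No biological explanation was tested.

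Sequence-determined binding might be expected at both homoeologous promoters where they share sequence. The observed share of 3.36% was not distinguishable from 2.99%. Peaks falling independently on A and D copies would give 2.99% if every copy were matched, and copies on differently numbered chromosomes were not. The interval of the observed share also leaves room for a share up to 5.13%. The same 20 pairs exceeded all 1000 shuffles of chromosome numbers (mean 5.54, highest 16). Homoeologs on same-numbered chromosomes would give such an excess even if their peaks were independent. Peaks missed in 1 copy near the detection limit stay open: 3 of 74 A genes with a pileup of 8 or more had a D partner against 17 of 521 with less (odds ratio 1.25, two-sided Fisher's exact test, p = 0.728), too few to decide. The 20 pairs that did occur, including those with a peak downstream of the start site, had more similar positions than shuffled partners. The median gap was 243 bp against a mean of 514 bp (two-sided permutation p = 0.013), so some of them may mark a shared site. However, 4 pairs within 100 bp were not beyond chance (1.91 expected, one-sided permutation p = 0.11).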
